A study of Mus musculus with 4 samples.

How the data were processed

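Small intestines of mice kept on a control or a ketogenic diet were dissociated, and single-cell 3' v2 libraries were made on the 10x platform, per the labels' protocols. Each diet had 2 libraries. The authors deposited a single matrix of raw UMI counts per gene and cell, with a table that gives each cell its library and 1 of 7 cell types. Cell Ranger 2.1.0 and the mm10 build are named in the submitters' processing notes. The filters on cells, the handling of doublets and the way cell types were assigned are not given in the sources used here. The deposited cell types were used as they stand, and no cells were clustered again.

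The matrix held 15053 cells and 27998 genes, of which 17972 had at least 1 UMI. The counts were the only values used, with no normalization by the authors to undo. Library names in the cell table equal the sample titles, and groups were taken from the diet label. The deposited table gives 1 donor name per library and that name is the library's own, so nothing states whether a library came from 1 animal or several. P-values therefore measure the spread between these libraries, which may be partly technical. The replicate libraries were not copies of each other, since a chi-square of their counts over genes was 30.1 times its degrees of freedom for the control pair and 22.6 times for the ketogenic pair.

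Counts were summed per library over all cells and over the cells of each type, because cells are not replicates. Every type had at least 20 cells in each library. The sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalization, filterByExpr by diet) in R 4.3.3, ketogenic against control, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use TMM-adjusted library sizes, and errors of log2 fold changes are standard errors derived from the fold change and the F statistic. The diet effect was compared between stem cells and enterocytes in 1 fit of 8 sums with library as a block. Cell numbers per type were tested with the same tool, with total cells as the offset. The exact permutation test of 2 against 2 libraries has 6 assignments, and its smallest two-sided p is 0.33.

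For gene lists, 48 lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of the symbols on the lists, 14 were not among the gene names. Lists with at least 4 measured members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01. The same lists were tested with a correlation estimated from the data and with fry. With 2 residual degrees of freedom the estimated correlation is imprecise. Camera then also takes its p from these 2 degrees of freedom, which raises it whatever the correlation. For the Notch pathway list in all cells, with an estimated correlation of -0.038, the unadjusted camera p was 0.230. With the fixed 0.01 it was 0.104. A call lost with an estimated correlation therefore does not show an effect of correlation between genes, nor that the call holds.

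Named genes are, in all cells, stem cells and enterocytes, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean log2 CPM of at least 5 and no overlap between diets. Up to 4 called members of each list and a fixed set of 11 genes of fat oxidation, stem cells and proliferation were added. Other cell types contribute up to 3 rises and 3 falls. Ribosomal, mitochondrially encoded and unnamed gene models enter only through a list. Results for some genes that this rule takes are not reported here, though counts of genes include them. Gene positions come from GENCODE M21, an annotation of the same genome build, matched by symbol for all 53 named genes. The annotation version behind the counts is not given in the sources used here. Defensin genes have near-identical copies among which counting can split or drop reads, so their values are uncertain.

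Scrublet in scanpy 1.11.5, run per library with an expected rate of 6%, called from 0.0204% to 0.188% of cells as doublets. A rate under 0.5% was taken as a sign that the caller had not worked, though doublets removed before deposit would give the same, so the 6% of cells with the highest scores were also left out, as an alternative chosen after seeing the data. Cells rich in Paneth transcripts were left out of the Paneth class as a further alternative of that kind. Other alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, only cells with mitochondrial UMIs under 10%, sums thinned to the lowest total, an equal mix of cell types, a replicate block and leaving out each library. Limits on RNA carried over from enterocytes, chosen after seeing the data, are Poisson upper limits at a one-sided 0.05 shared over 7 markers. Where a library is left out, the lone library of its diet is assumed to vary like the other 2.

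The tests were checked on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes changed. The changed genes were drawn from well expressed genes alone. They outnumber the real calls, which eases the adjusted threshold, so recovery of real changes can be lower. In real enterocytes Cpt1a, at a log2 fold change of 0.99 ± 0.16, did not pass (adjusted p = 0.0954 by edgeR). For stem cells (9514 genes), edgeR recovered 93 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 4 false calls among 197. For enterocytes (11697 genes) it recovered 99 of 100 and 100 of 100, with 26 false calls among 225, more than the threshold implies. For all cells (12784 genes) it recovered 98 and 100 of 100, with 26 false calls among 224, so some calls in these comparisons may be false. The simulated difference between stem cells and enterocytes (10983 genes) was recovered for 54 of 100 genes at 2-fold and 100 of 100 at 4-fold, with 13 false calls among 167, also above what the threshold implies. Transit amplifying cells (10069 genes) had 12 false calls among 211 and goblet cells (9984 genes) 15 among 215. DESeq2 also made more false calls than the threshold implies in all cells (19 among 217) and enterocytes (20 among 219). It made 2 among 182 in stem cells, 2 among 197 in transit amplifying cells and 1 among 196 in goblet cells. In stem cells it recovered 80 of 100 genes changed 2-fold. In 20 simulations of stem cells with no change, camera called 2 of 820 lists. Those simulations draw genes independently, so they do not test the effect of correlation between genes.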

Results

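Single-cell transcriptomes of the small intestine were compared between mice on a control diet and mice on a ketogenic diet, a regime of high fat and very low carbohydrate that induces the synthesis of ketone bodies. Control libraries 1 and 2 held 3549 and 4896 cells with 29186729 and 34106639 UMIs. Ketogenic libraries 1 and 2 held 3194 and 3414 cells with 27316428 and 30292457 UMIs. The median cell had 8077 and 6974.5 UMIs in the control libraries and 8734.5 and 9040.0 in the ketogenic libraries. All cells carried 1 of 7 epithelial annotations: stem, transit amplifying, enterocyte, goblet, Paneth, enteroendocrine or tuft. Summed over a library, stem cells gave 1712487 to 3400566 UMIs, enterocytes 14946235 to 19465885 and the Paneth class 289338 to 526414. Cells with 50% or more mitochondrial UMIs made up 3.47% and 2.70% of the control libraries and 8.14% and 4.63% of the ketogenic libraries.

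The first comparison asked how the diet changed the whole epithelium. Acot1, an acyl-CoA thioesterase (chromosome 12, 84009490 to 84018371, plus strand, mm10), rose 5.73-fold, with a log2 fold change of 2.52 ± 0.27 (SE, n = 2 libraries per diet, adjusted p = 0.0327 by edgeR). Its level was 27.6 and 42.2 CPM in the control libraries and 242 and 158 CPM in the ketogenic libraries. Mgll, a monoglyceride lipase, and Acadl, a mitochondrial acyl-CoA dehydrogenase, rose by 2.26 ± 0.22 and 0.82 ± 0.09 on the log2 scale. The disaccharidase Sis, the glucose transporter Slc2a2 and the triokinase Tkfc fell, with log2 fold changes of -3.02 ± 0.26, -3.57 ± 0.24 and -1.13 ± 0.11. The glycolytic pyruvate kinase Pkm also fell (-1.13 ± 0.09).

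Of 32 measured PPAR target genes, which the fatty acid sensing PPAR receptors induce, 4 rose in the summed epithelium and 0 fell, and 23 rose when adjusted over the list alone (camera adjusted p = 4.62e-17, and adjusted p = 0.532 with an estimated correlation). Of 12 genes for carbohydrate digestion and sugar transport, 4 fell and 0 rose, and 11 fell when adjusted over the list alone (camera adjusted p = 1.52e-13, and adjusted p = 0.532 with an estimated correlation). Of 18 interferon response genes, Ifit1, Isg15 and Oasl2 fell, with log2 fold changes of -2.59 ± 0.27, -1.71 ± 0.18 and -1.17 ± 0.12, and 5 fell when adjusted over the list alone (camera adjusted p = 4.95e-10, and adjusted p = 0.532 with an estimated correlation). The median log2 fold change of the interferon list was -0.78, and -0.33 without control library 1. Of 20 antimicrobial peptide genes, Mptx2, Defa23, Defa26 and Reg4 rose by 3.02 ± 0.32, 2.76 ± 0.29, 2.15 ± 0.15 and 1.74 ± 0.15. Adjusted over the list alone, 11 rose and 3 fell (camera adjusted p = 0.000488, and adjusted p = 0.532 with an estimated correlation). The antimicrobial list lost its camera call without control library 2 (median log2 fold change 1.20 against 1.10), and without control library 1 its median was 1.74. Defensin genes have near-identical copies, so their values are uncertain.

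Marker lists of the 4 secretory cell types were higher in the summed epithelium as well. Some members are also on the antimicrobial list, so these results are not separate from it. They include Mptx2 and Defa26 of the Paneth list and Reg4 of the enteroendocrine list, the genes of these lists called by edgeR. All 13 Paneth cell, 21 enteroendocrine and 15 tuft cell genes and 15 of 16 goblet cell genes were higher, with median log2 fold changes of 1.94, 0.91, 0.45 and 0.36 (camera adjusted p = 3.41e-09, 7.42e-07, 1.27e-09 and 1.70e-06). With an estimated correlation the adjusted p was 0.532, 0.603, 0.532 and 0.603. By edgeR 2, 1, 0 and 0 of them rose, against 9, 14, 14 and 10 at an unadjusted p under 0.05, 5, 2, 2 and 4 by DESeq2, and 9, 1, 14 and 9 adjusted over the list alone. Without ketogenic library 1 the Paneth, enteroendocrine and tuft medians were 1.16, 0.22 and 0.30, and without ketogenic library 2 the goblet median was 0.56. The shares of captured Paneth, enteroendocrine, tuft and goblet cells were also higher, by log2 ratios of 0.46, 0.83, 0.52 and 0.25, none past the threshold by edgeR against 1 at an unadjusted p under 0.05. Leaving out each library moved the enteroendocrine ratio from 0.19 (without ketogenic library 1) to 1.27 (without control library 2) and the Paneth ratio from 0.20 to 0.68 (without ketogenic libraries 1 and 2). Cells with 30% or more of their UMIs in the Paneth list numbered 1 and 2 in control and 10 and 8 in ketogenic libraries. Changes of these lists in the summed epithelium can therefore include differences in cell numbers. With an equal mix of cell types in every library Mptx2, Defa23 and Defa26 were not called, at log2 fold changes of 3.09, 2.84 and 2.15. These lie close to the 3.02, 2.76 and 2.15 from all cells, so the equal mix did not lower them. It does not equalize the number of Paneth-rich cells within the Paneth class.

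In all, 22 of 12784 genes changed in the summed epithelium, 11 up and 11 down, and DESeq2 called 203, which included all 22. The count was 120 without control library 1, 364 without control library 2 and 39 without ketogenic library 1. Of the 22 genes, 11 were called again without ketogenic library 2, where Pkm, Tkfc, Ifit1, Oasl2, Acadl and Defa23 lost their calls, and 19 without ketogenic library 1, where Acadl, Tkfc and Oasl2 did. All 22 kept their direction in each of these fits. Acadl and Isg15 were also not called without the 6% of cells with the highest doublet scores (log2 fold changes of 0.81 and -1.73) or with only cells under 10% mitochondrial UMIs (0.77 and -1.64), and with that limit neither was Mptx2 (3.23). These values lie close to those from all cells, and their adjusted p-values ran from 0.0509 to 0.0536. Fabp1, a fatty acid binding protein, had a log2 fold change of 2.51 ± 0.32 that did not pass (adjusted p = 0.0553 by edgeR), though it did in 7 of 13 alternatives. Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, did not pass either (0.89 ± 0.13, adjusted p = 0.0738 by edgeR), though it did in 6 of 13.

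Stem cells were examined because the series concerns intestinal tumorigenesis. Fabp1 (chromosome 6, 71199827 to 71205023, plus strand) rose 10.8-fold, with a log2 fold change of 3.44 ± 0.19 (adjusted p = 1.13e-11 by edgeR), from 49.5 and 62.1 CPM in control to 768 and 464 CPM in ketogenic libraries. Creb3l3, a transcription factor of lipid metabolism, rose by 2.82 ± 0.35 and Acot1 by 1.75 ± 0.14. The mitochondrial beta-oxidation enzymes Acadl, Acadvl, Eci2 and Acaa2 rose by 1.17 ± 0.15, 0.79 ± 0.13, 0.83 ± 0.13 and 0.71 ± 0.12, and Cpt1a by 0.88 ± 0.17. Sgk1, Klf9, Retsat, Herpud1 and Fabp2 also rose, by 1.16 ± 0.17, 0.88 ± 0.15, 1.00 ± 0.18, 0.73 ± 0.13 and 0.62 ± 0.13. Sis fell (-2.25 ± 0.30), as did Scd2, a fatty acid desaturase (-1.54 ± 0.25), Smim24 (-0.89 ± 0.12), Clca4b (-0.81 ± 0.16) and Ybx3 (-0.81 ± 0.15).

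Among 24 measured PPAR target genes, 14 rose in stem cells by edgeR, 0 fell and 10 did not pass. DESeq2 called 6 rises, and 20 rose when adjusted over the list alone. Camera placed this list above other genes (adjusted p = 1.90e-22), a call lost with an estimated correlation (adjusted p = 0.631). Of 24 mitochondrial fatty acid oxidation genes, 7 rose by edgeR, against 4 by DESeq2, and 0 fell, and 13 rose when adjusted over the list alone (camera adjusted p = 9.57e-09, and adjusted p = 0.631 with an estimated correlation). Members such as Acadl, Acaa2 and Cpt1a are on both lists, so the 2 calls are not independent. These 2 lists and that of peroxisomal fatty acid oxidation were the 3 of 10 stem cell lists that camera still called without control library 1. Of 12 genes of fatty acid uptake and binding, Fabp1 and Fabp2 alone passed by edgeR, against 1 rise by DESeq2, and camera did not call the list (adjusted p = 0.176). Of the 41 to 44 lists tested in all cells, stem cells and enterocytes, 0 kept a camera call with an estimated correlation, against 0, 1 and 0 lists at an unadjusted p under 0.05 and 0 lists by fry. The stem cell markers Lgr5 and Olfm4 did not pass, at log2 fold changes of -0.07 ± 0.12 and 0.07 ± 0.14 (adjusted p = 0.978 for both by edgeR). The proliferation marker Mki67 was at -0.20 ± 0.16 (adjusted p = 0.921). A missed threshold does not show that these genes were unaffected.

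In stem cells 32 of 9514 genes changed, 25 up and 7 down, and DESeq2 called 12, all among the 32. Retsat, Klf9, Cpt1a, Herpud1, Fabp2, Ybx3 and Clca4b were not called by DESeq2. The count was 84 without control library 1, 100 without control library 2 and 53 without ketogenic library 2. Fabp2 was not called without control library 1 or ketogenic library 1 (log2 fold changes of 0.42 and 0.60), Cpt1a without ketogenic library 1 (0.68), and Ybx3 without control library 2 (-0.49). Without control library 1 the log2 fold change of Scd2 was -1.02. With only cells under 10% mitochondrial UMIs Sis, Scd2, Retsat, Cpt1a, Fabp2 and Clca4b were not called, at log2 fold changes of -2.40, -0.97, 0.84, 0.69, 0.44 and -0.86, so those of Sis and Clca4b were no smaller than with all cells. This limit removed 52.2% and 44.0% of the stem cells in control libraries 1 and 2, and 59.8% and 45.7% in ketogenic libraries 1 and 2. Without the 6% of cells with the highest doublet scores Fabp2 was not called (0.57). If it has the average profile of enterocytes, carried-over RNA can bring each of their transcripts to stem cells at no more than a set ratio. That ratio is the lowest stem to enterocyte ratio of 7 enterocyte markers. RNA from immature enterocytes was not tested. Of the called genes named here, all 13 rises exceeded the upper limit of that ratio in both ketogenic libraries, relative to their change in enterocytes. Of 6 falls, those of Ybx3, Clca4b, Smim24 and Scd2 exceeded it in both control libraries. For Cd74 the ratio has no meaning in control library 2. Its stem cell level there (75.6 CPM) lay under both ketogenic libraries (87.1 and 108 CPM). Sis did not exceed the limit in both control libraries. Its control level in stem cells was 0.0395 and 0.0549 of that in enterocytes, against lowest marker ratios of 0.0434 and 0.0378.

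The antigen presentation gene Cd74 (chromosome 18, 60803848 to 60812652) was lower in ketogenic stem cells by edgeR (log2 fold change -2.57 ± 0.56, adjusted p = 0.0416). The level was 1120 CPM in control library 1 against 75.6 CPM in control library 2, and 87.1 and 108 CPM in the ketogenic libraries. Without control library 1 the log2 fold change was 0.40, so the difference rested on that library. It was not called by DESeq2, or by edgeR without the 6% of cells with the highest doublet scores (-2.55). All 7 measured members of the MHC class II list were lower in stem cells, with only Cd74 past the threshold, and 6 fell when adjusted over the list alone (camera adjusted p = 0.0393, and adjusted p = 0.849 with an estimated correlation). Without control library 1 the median log2 fold change of the list was also 0.40, and without ketogenic library 1 its camera call was lost at a median of -2.38. The interferon response list was lower in stem cells as well (camera adjusted p = 0.000136, and adjusted p = 0.631 with an estimated correlation). None of its 10 members passed by edgeR or DESeq2, 6 were lower at an unadjusted p under 0.05 and 2 fell when adjusted over the list alone. Its median log2 fold change was -0.53. Its call too was lost without control library 1, with a median of -0.15, and the median was -1.02 without control library 2 and -0.82 without ketogenic library 2.

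Enterocytes, which absorb dietary fat, were examined next. Acot1 rose 7.37-fold (log2 fold change 2.88 ± 0.32, adjusted p = 0.0366 by edgeR) and Acadl rose by 0.85 ± 0.10. The fatty acid hydroxylase Cyp4a10 rose by 5.01 ± 0.61, Mgll by 4.32 ± 0.35 and Akr1b8, an aldo-keto reductase, by 2.59 ± 0.23. In the control libraries Cyp4a10 lay at only 0.218 and 0.466 CPM and Mgll at 0.327 and 0.518 CPM, so the size of these rises is uncertain. Sis (chromosome 3, 72888557 to 72967863, minus strand) went from 587 and 436 CPM to 70.1 and 47.1 CPM, a log2 fold change of -3.13 ± 0.23. Slc2a2 fell (-3.76 ± 0.28), as did Pkm (-1.33 ± 0.11) and Tkfc (-1.15 ± 0.13). The cytokine Il18 fell (-1.82 ± 0.13), and so did Papss2 (-1.68 ± 0.18), the monocarboxylate transporter family member Slc16a6 (-1.79 ± 0.19), Ifit1 (-3.98 ± 0.34) and Oasl2 (-1.53 ± 0.17). Ifit1 lay at only 0.277 and 0.414 CPM in the ketogenic libraries, so the size of its fall is uncertain. The defensin gene Defa21, which has near-identical copies and is abundant in Paneth cells, rose by 1.28 ± 0.16. Fabp1 was higher by 2.60 ± 0.34 and did not pass (adjusted p = 0.0518), though it did in 11 of 12 alternatives, over which its adjusted p ran from 1.69e-06 to 0.0529. Pdk4, a kinase that restrains glucose oxidation, had 0 UMIs in control and 108 in ketogenic enterocytes, at least 43.2-fold higher against a floor of 3 counts over the control group. Its ketogenic levels were 6.02 and 1.24 CPM, and the limit was 16.0-fold and 73.0-fold without ketogenic libraries 1 and 2 and 22.3-fold and 20.8-fold without control libraries 1 and 2. Its edgeR test did not pass (adjusted p = 0.164), though it did in 6 of 12 alternatives.

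Of 12 measured genes for carbohydrate digestion and sugar transport, 4 fell in enterocytes and 0 rose, and adjusted over the list alone 11 fell (camera adjusted p = 7.17e-14, and adjusted p = 0.613 with an estimated correlation). Of 31 PPAR target genes, 5 rose and 0 fell, and 25 rose when adjusted over the list alone (camera adjusted p = 5.77e-19, and adjusted p = 0.613 with an estimated correlation). Of 25 mitochondrial fatty acid oxidation genes, Acadl alone passed by edgeR, against 9 rises by DESeq2, and 11 rose when adjusted over the list alone (camera adjusted p = 1.48e-06, and adjusted p = 0.613 with an estimated correlation). All 26 measured cholesterol synthesis genes were lower, with a median log2 fold change of -0.64. Of them 0 passed by edgeR, against 19 at an unadjusted p under 0.05, 9 by DESeq2 and 18 adjusted over the list alone (camera adjusted p = 1.66e-14, and adjusted p = 0.613 with an estimated correlation). Without control library 1 the median of this list was -0.38. Of 17 interferon response genes, Ifit1 and Oasl2 fell, and 9 fell when adjusted over the list alone (camera adjusted p = 6.81e-11, and adjusted p = 0.613 with an estimated correlation). The median log2 fold change of the interferon list was -0.94, and it was -0.68 without control library 1 and -1.52 without control library 2. Enterocytes of control library 1 held 12338 UMIs of Cd74, against 336 to 679 in the other libraries. Of 15 fatty acid synthesis genes, Me1, a malic enzyme that yields NADPH, and Acacb, an acetyl-CoA carboxylase whose product inhibits mitochondrial fatty acid uptake, rose by 3.15 ± 0.34 and 3.03 ± 0.38. Camera nonetheless placed that list below other genes, with a median log2 fold change of -0.22 and 2 rises and 4 falls adjusted over the list alone (camera adjusted p = 0.0432, and adjusted p = 0.613 with an estimated correlation). This call was lost without any 1 of the 4 libraries, at medians of -0.11 and -0.23 without control libraries 1 and 2 and -0.14 and -0.16 without ketogenic libraries 1 and 2.

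The 29 nuclear oxidative phosphorylation genes were all lower in enterocytes, with a median log2 fold change of -0.23. Of them 0 passed by edgeR, by DESeq2 or adjusted over the list alone, against 7 at an unadjusted p under 0.05 (camera adjusted p = 1.48e-08, and adjusted p = 0.613 with an estimated correlation). Cells with 50% or more mitochondrial UMIs made up 4.45% and 3.93% of control and 12.7% and 7.28% of ketogenic enterocytes. The list of 13 proximal small intestine genes was lower, with Slc2a2 past the threshold and 7 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.00163, and adjusted p = 0.613 with an estimated correlation). This call was lost without control library 2 (median log2 fold change -0.36) and without ketogenic library 2 (-0.56). Transcripts of the distal marker Fabp6, named here after its values were seen, lay at 274 CPM in enterocytes of control library 1 against 56.7 CPM in control library 2 and 124 and 121 CPM in the ketogenic libraries.

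Lists of genes active in less mature cells were also compared in enterocytes. Of 21 intestinal stem cell genes 20 were higher, with a median log2 fold change of 0.34 (camera adjusted p = 0.00149, and adjusted p = 0.727 with an estimated correlation). Of 15 Wnt target genes 12 were higher, with a median of 0.36 (camera adjusted p = 0.00610, and adjusted p = 0.716 with an estimated correlation). No member of either list passed by edgeR or DESeq2, against 5 and 6 at an unadjusted p under 0.05 and 0 and 2 adjusted over the list alone. Both calls were lost without control library 1 (medians of 0.05 and 0.12) and without ketogenic library 2 (0.12 and 0.21), and the Wnt median was 0.62 without control library 2. A rise was not particular to these lists. Camera also placed the Paneth, tuft, enteroendocrine and goblet lists above other genes in enterocytes (adjusted p = 7.55e-06, 0.000367, 0.0325 and 0.0334, and 0.613 for each with an estimated correlation). Over the alternatives their medians ran from 0.53 to 1.25, 0.32 to 0.81, 0.12 to 0.77 and 0.060 to 0.31. The goblet call was lost without control library 1 (median 0.060) and without ketogenic library 1 (0.16). The enteroendocrine call was lost with the replicate block (0.38) and without ketogenic library 1 (0.12). Of 12 villus tip genes 9 were lower, and camera did not call the list (adjusted p = 0.478). Dissociation and immediate early genes were lower in 12 of 16 members, with a median of -0.31, and -0.20 without control library 1 (camera adjusted p = 0.00163, and adjusted p = 0.613 with an estimated correlation). None of them passed by edgeR, against 1 rise and 5 falls at an unadjusted p under 0.05 and 1 rise and 3 falls both by DESeq2 and adjusted over the list alone.

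In enterocytes 21 of 11697 genes changed, 9 up and 12 down, and DESeq2 called 174, including all 21. The count was 228 without control library 1, 760 without control library 2, 12 without ketogenic library 1 and 32 without ketogenic library 2. Of the 21 genes, 10 were called again without ketogenic library 1 and 12 without ketogenic library 2, and all 21 kept their direction. Acadl, Tkfc, Oasl2, Slc16a6 and Defa21 were not called without either ketogenic library, Pkm, Ifit1 and Acacb not without ketogenic library 1, and Papss2 not without ketogenic library 2.

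**Figure D1:**
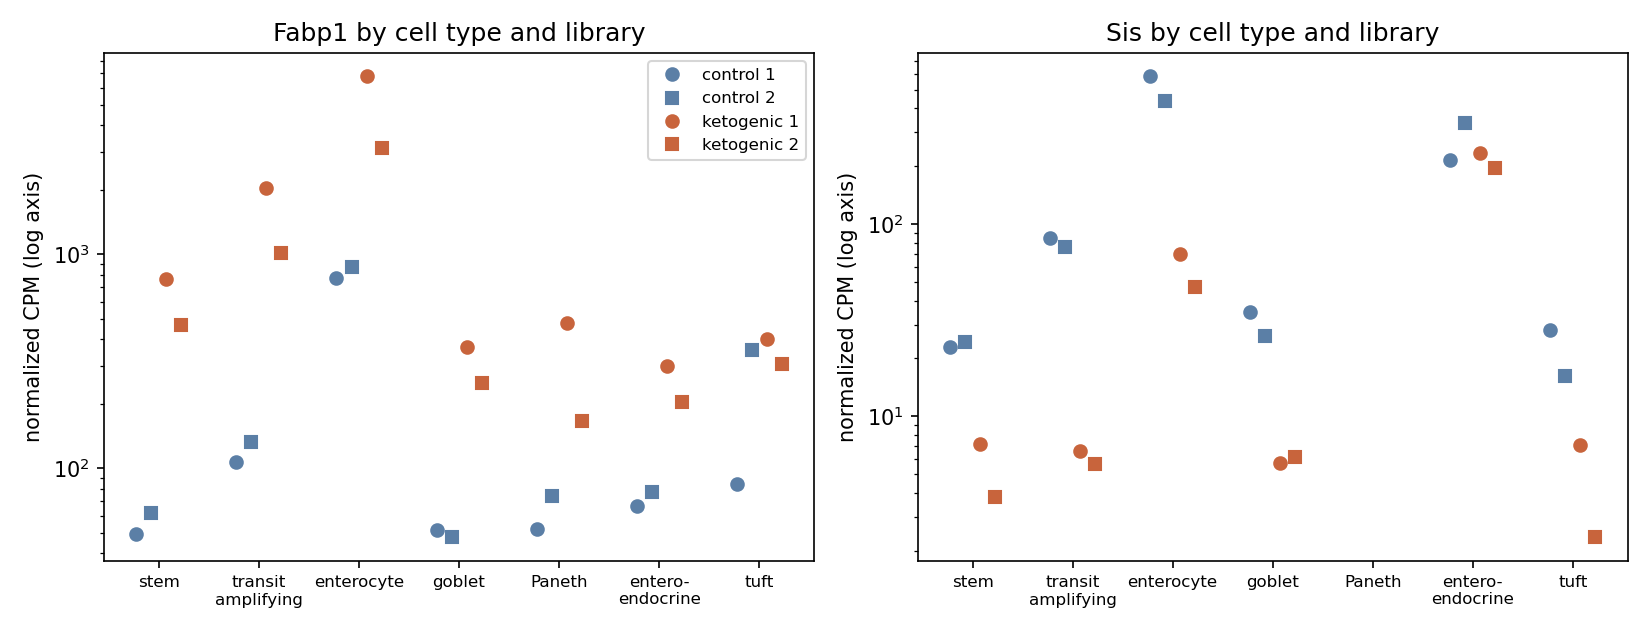
Normalized CPM of Fabp1 (left) and Sis (right) on log axes, by cell type, with 1 point per library. Both ketogenic libraries lie above both control libraries for Fabp1 in every type but tuft cells, where the diets overlap, while Sis in enteroendocrine cells lies between 195 and 334 CPM in all 4 libraries and was not tested in Paneth cells.

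Whether the diet effect differed between stem cells and enterocytes was tested directly. Acot1 had a higher log2 fold change in enterocytes, by 1.06 ± 0.16 (adjusted p = 9.68e-05 by edgeR). Fabp1 had a lower log2 fold change in enterocytes (difference -0.94 ± 0.14, adjusted p = 4.05e-05). Pkm and Tkfc also had lower values in enterocytes, with differences of -0.94 ± 0.15 and -0.88 ± 0.19. The smallest p-values belonged to Reg3b and Reg3g, antibacterial lectins named here after their values were seen, with differences of -1.66 ± 0.14 and -1.76 ± 0.15. The difference passed for 30 of 11570 genes, 7 with a higher log2 fold change in enterocytes and 23 with a lower. The count was 358 without control library 2, 18 without control library 1 and 14 without ketogenic library 2. Without ketogenic library 2 the differences of Fabp1 and Tkfc did not pass (-0.71 and -0.54).

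**Figure D2:**
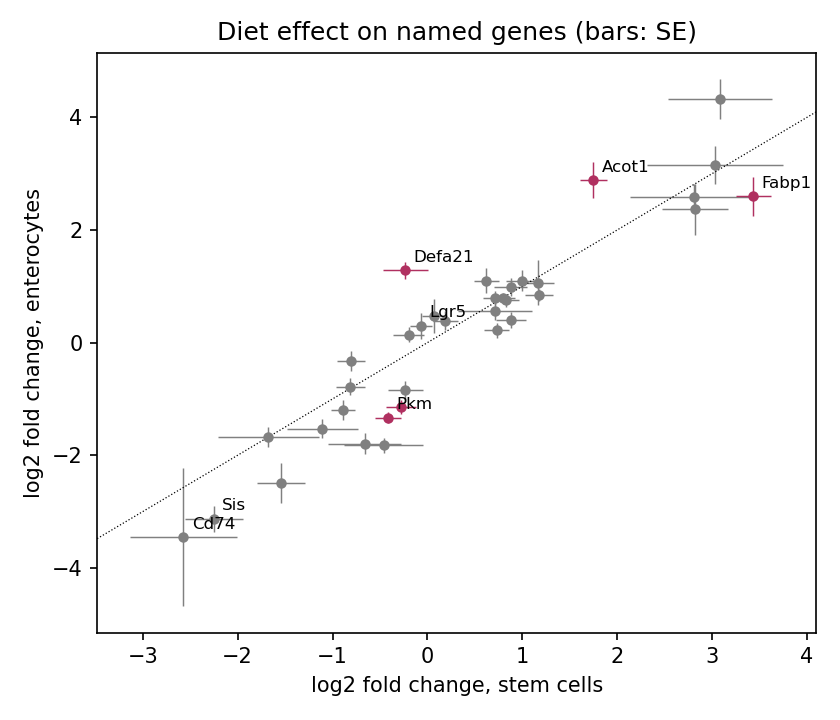
Log2 fold change, ketogenic minus control, in stem cells (horizontal) and enterocytes (vertical) for genes named in either, with standard errors as bars and a dotted line of equality. Red points passed the test of the difference, among them Acot1 above the line and Fabp1 and Pkm below it. Pdk4 is left out.

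The other cell types were fitted separately. Fabp1, Acot1, Acadl and Mgll rose in 4 types, Sis fell in 4, and Scd2 and Smim24 fell in 3. In transit amplifying cells 72 of 10069 genes changed, 46 up and 26 down, with rises of 3.67 ± 0.26 for Fabp1 and 2.62 ± 0.22 for Acot1. Sis, Scd2 and Adh6a fell there, with log2 fold changes of -3.71 ± 0.16, -2.18 ± 0.26 and -1.46 ± 0.19. In goblet cells 52 of 9984 genes changed, 31 up and 21 down. Fabp1 and Acot1 rose by 2.64 ± 0.15 and 2.26 ± 0.26. Scd2, Adh6a and Mvd, an enzyme of cholesterol synthesis, fell in goblet cells (-2.23 ± 0.16, -1.17 ± 0.17 and -0.78 ± 0.15), Mvd not by DESeq2. Enteroendocrine cells had 4 of 6877 genes changed, 2 up and 2 down. Fabp1 rose by 1.81 ± 0.22, and Reg3b and Reg3g fell (-2.89 ± 0.39 and -3.31 ± 0.46), the falls not by DESeq2. The limit from enterocyte markers leaves room for carried-over RNA to make up 0.971 or more of the Fabp1 gain in goblet and enteroendocrine cells. In tuft cells 1 of 6963 genes passed by edgeR, a rise, against 372 genes at an unadjusted p under 0.05 and 2 called by DESeq2. The 372 genes are close to the number expected at that p if no gene changed.

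The number of calls in these types moved with single libraries. Without control libraries 1 and 2 transit amplifying cells had 220 and 290 calls, goblet cells 189 and 180, enteroendocrine cells 37 and 94, and tuft cells 37 and 6. Without ketogenic library 1 these types had 37, 99, 11 and 29 calls. Without ketogenic library 2 goblet cells had 121, enteroendocrine cells 18 and tuft cells 14.

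In the Paneth class 13 of 2957 genes rose and 0 fell by edgeR, against 91 falls at an unadjusted p under 0.05 and 0 falls by DESeq2. The 91 falls are not far above the number expected at that p if no gene changed. Mptx2 rose by 3.92 ± 0.46 and Defa23 by 3.11 ± 0.31. The goblet list held a median of 8.59% and 9.92% of a cell's UMIs in control and 10.5% and 8.30% in ketogenic libraries, more than the Paneth list at 2.96%, 2.55%, 3.62% and 3.34%. Cells with 30% or more of their UMIs in the Paneth list numbered 1 and 2 in control and 10 and 8 in ketogenic libraries. Without them 2 genes were called and 8 of the 13 were tested, 5 in the same direction, though leaving out cells by this list partly sets the outcome for its genes. Without ketogenic library 1 the class had 2 calls, and Defa23 was not among them (log2 fold change 3.36). Without control libraries 1 and 2 it had 23 and 31 calls, and Mptx2 was not called without control library 1 (3.94).

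Shares of captured cells were compared last. Tuft cells made up 2.36% ± 0.19 (SD, n = 2) of control and 3.40% ± 0.33 of ketogenic cells, a log2 ratio of 0.52 ± 0.16 (SE, adjusted p = 0.207 by edgeR on cell numbers). Enterocytes made up 58.7% ± 2.9 and 53.7% ± 1.4, transit amplifying cells 13.2% ± 0.92 and 11.8% ± 0.81, goblet cells 12.3% ± 0.99 and 14.6% ± 0.45, and Paneth cells 1.06% ± 0.11 and 1.48% ± 0.35. Stem cells made up 10.1% ± 1.8 and 10.7% ± 3.9. Enteroendocrine cells were 2.40% ± 0.88 and 4.30% ± 2.2, with an adjusted p of 0.252 by edgeR. No type passed the threshold by edgeR, against 1 at an unadjusted p under 0.05, and the exact permutation test cannot give a two-sided p under 0.33 here. The enteroendocrine share passed only without ketogenic library 2 (log2 ratio 1.26, adjusted p = 0.0222 by edgeR, within a range of 0.0222 to 0.717 over its alternatives).

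**Figure D3:**
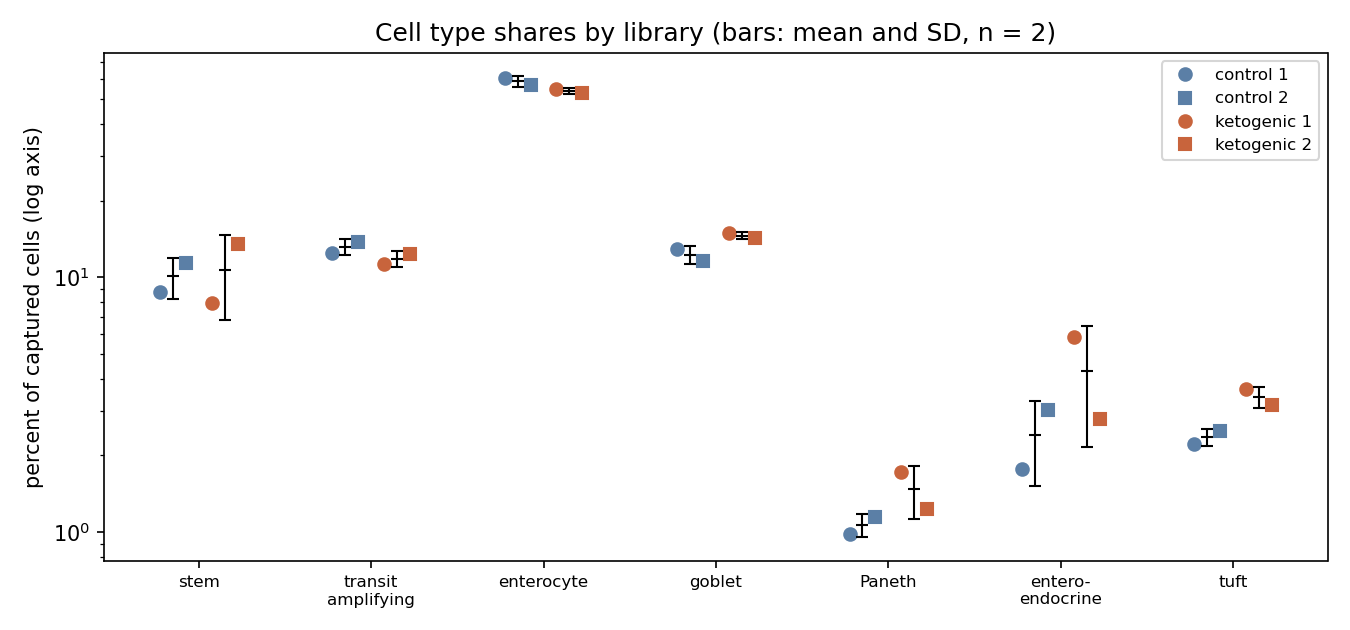
Percent of captured cells in each type on a log axis, with 1 point per library and bars for the mean and SD of 2 libraries per diet. Both ketogenic libraries lie above both control libraries for tuft, goblet and Paneth cells, and the diets overlap for stem and enteroendocrine cells.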

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

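The tests of explanations below were all chosen after the patterns had been seen, while the test of the diet effect between stem cells and enterocytes was planned. That test passed for 30 genes. Among the named genes, the difference of enterocytes minus stem cells was 1.06 for Acot1 and 1.47 for Defa21 on the log2 scale. It was -0.94 for Fabp1, -0.94 for Pkm and -0.88 for Tkfc. The differences of Fabp1 (-0.71), Tkfc (-0.54) and Defa21 (1.31) did not pass without ketogenic library 2, nor that of Defa21 without control library 1 (1.09). Sis also differed between enteroendocrine cells and enterocytes, by 2.71 ± 0.21 (adjusted p = 1.09e-16 by edgeR), a comparison added after its values were seen. Defa21 has near-identical copies and its enterocyte level can include RNA released by Paneth cells.

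Fabp1 rose in stem, transit amplifying, goblet and enteroendocrine cells, which raises the question of enterocyte RNA carried into other droplets, free or through doublets. Carried-over RNA would bring all enterocyte transcripts in the same ratio, so the lowest ratio among 7 enterocyte markers limits it. Its upper limit, from counting error over the 7 markers, allowed at most 0.525 of the Fabp1 gain in stem and transit amplifying cells of the ketogenic libraries, which argues against carry-over as the whole cause there. That limit assumes RNA with the average profile of enterocytes, and RNA from immature enterocytes was not tested. In goblet cells the limits were 0.982 and 0.971 of the gain, and in enteroendocrine cells 2.54 and 1.80, with the lowest markers at 0 to 12 UMIs. The lowest marker ratios lay under the Fabp1 ratio in goblet cells (0.0274 and 0.0442 against 0.0545 and 0.0864) and enteroendocrine cells (0.0314 and 0.0 against 0.0374 and 0.0533). Carry-over as the whole cause and a rise within these cells therefore cannot be told apart, because the limits lie near or above the whole gain. The fall of Sis in stem cells stays open in the same way, since its change ratio was 0.0337 and 0.0489 against upper limits of 0.0568 and 0.0480 in the control libraries.

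Cd74 was lower in ketogenic stem cells, and 1 control library stands apart: without control library 1 the log2 fold change was 0.40. The lowest control level was 0.867 times the lowest ketogenic level, so the control libraries lay on either side of the ketogenic ones. Whether diet played a part cannot be decided, because the difference rests on control library 1 and nothing shows which control library is typical. Immune cells among the annotated stem cells are argued against as its source. The median stem cell of control library 1 had 596 CPM of Cd74, and that of every other library had 0.0. What set control library 1 apart was not tested and the labels record no batch.

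The Paneth list was higher in the Paneth class of both ketogenic libraries. The median share per cell was only 1.27 times higher, against 2.88 times for the summed share, which argues against a rise in most cells. Cells with a share of 30% or more made up 18.2% or more of the class in ketogenic and at most 3.57% in control libraries. More such cells may account for the summed rise. Without the top cell of each library the ratio was 4.66. It was raised in part because control library 1 lost its only such cell (summed share 11.9% with it, 4.75% without). The ketogenic shares without their top cells, 22.3% and 17.5%, still lay above the control shares with all cells, 11.9% and 5.38%. The ketogenic rise therefore did not rest on 1 large cell. The limit of 30% was set after seeing the shares: 1, 0, 3 and 1 cells of the 4 libraries lay between 20% and 40%, and the numbers were 2, 2, 13 and 8 at 20% and 1, 2, 10 and 7 at 40%. Whether diet or the capture of Paneth cells set these numbers cannot be told apart, because both change with the library.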

How the results depend on the processing

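Leaving out the 6% highest doublet scores or the Paneth-rich cells, and the mitochondrial limit in types other than stem cells and enterocytes, were alternatives chosen after seeing the data. Among genes taken by the naming rule, 12 calls were lost by DESeq2, 10 with the mitochondrial limit, 6 without the highest doublet scores, and 17 and 18 without ketogenic libraries 1 and 2, all in the same direction. With no filter on low counts the calls were 407 in all cells, 74 in stem cells, 313 in enterocytes and 49 for the difference between stem cells and enterocytes. DESeq2 called 203 in all cells, 12 in stem cells, 55 in transit amplifying cells, 174 in enterocytes, 24 in goblet, 11 in Paneth, 2 in enteroendocrine and 2 in tuft cells. Thinning gave 53 in stem cells and 33 in enterocytes. The mitochondrial limit gave 51 in enterocytes and 20 in Paneth cells. Without the highest doublet scores enterocytes had 37 calls, and without Paneth-rich cells the Paneth class had 2. The cause of these differences was not tested. The automatic doublet calls removed at most 6 cells per library, and the denominator of epithelial cells equals that of all cells, so neither says anything about stability. No list call in all cells, stem cells or enterocytes held with an estimated correlation (0 lists) or by fry (0 lists). With the estimated correlation, p-values from 2 degrees of freedom made a pass unlikely from the start. Its losses do not show an effect of correlation between genes.

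The libraries share numbers 1 and 2 across diets, and the labels do not say whether these numbers pair them. Deviations of same-numbered libraries correlated across genes between -0.0374 and 0.0828. This gives no sign of a pairing but cannot exclude one. With the replicate block the calls were 69 in all cells, 99 in stem, 200 in transit amplifying, 137 in enterocytes, 104 in goblet, 57 in Paneth, 19 in enteroendocrine and 4 in tuft cells.

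Leaving out each library moved the calls from 29 to 364 in all cells (lowest without ketogenic 2), 48 to 100 in stem cells and 12 to 760 in enterocytes (both lowest without ketogenic 1), all highest without control 2. The ranges were 37 to 290 in transit amplifying, 99 to 189 in goblet, 2 to 31 in Paneth, 11 to 94 in enteroendocrine and 6 to 37 in tuft cells, and 14 to 358 for the difference between types. List calls ranged from 3 to 9 in stem cells and 15 to 26 in enterocytes, lowest without control 1. Fewer libraries, and the loss of a library's spread, are part of each change.

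Directions turned for the results here, of which only Cd74 and the lists were called. The log2 fold change of Olfm4 ran from -0.20 to 0.76 in all cells, -0.12 to 0.22 in stem cells and -0.0051 to 0.84 in enterocytes. That of Lgr5 ran from -0.27 to 0.39, -0.14 to 7.3e-05 and -0.00041 to 0.68 (passing without control 2), and that of Mki67 from -0.20 to 0.0029 in all cells and -0.0050 to 0.28 in enterocytes. Cd74 in stem cells ran from -3.49 to 0.40. The list medians ran from -3.56 to 0.30 (MHC class II, all cells), -3.42 to 0.40 (MHC class II, stem), -3.91 to 0.15 (MHC class II, enterocytes), -0.0020 to 0.26 (villus tip enterocyte, stem), -0.63 to 0.19 (MHC class I, stem), -0.028 to 0.18 (ribosomal proteins, all cells) and -6.25 to 0.20 (T cell, enterocytes). The log2 share ratio of stem cells ran from -0.35 to 0.41. That of enteroendocrine cells did not turn (0.19 to 1.27). The cause was not tested.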

Other observations

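The list tests here were planned, while leaving out libraries for them and the look at sex-linked genes were chosen after the values were seen. In transit amplifying cells, 4 of 26 measured cholesterol synthesis genes fell and 0 rose, and 13 fell when adjusted over the list alone (camera adjusted p = 1.05e-11, and adjusted p = 0.363 with an estimated correlation). The members past the threshold included Fdft1, Hmgcs1 and Sqle. In goblet cells 4 of 26 fell, among them Hmgcs1, Fdft1 and Mvd, and 14 fell when adjusted over the list alone (camera adjusted p = 7.69e-11, and adjusted p = 0.486 with an estimated correlation). In goblet cells 3 of 13 interferon response genes fell, Isg15, Ifit1 and Irf7, and 7 fell when adjusted over the list alone (camera adjusted p = 4.76e-09, and adjusted p = 0.443 with an estimated correlation). Goblet cells of control library 1 held 962 UMIs of Cd74 against 27 to 48 in the other libraries, and without that library the median log2 fold change of the interferon list was -0.50 against -0.65, with the camera call kept. Of 16 unfolded protein response genes in transit amplifying cells, Hspa5, Manf and Creld2 fell while Herpud1 rose, with 8 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.000257, and adjusted p = 0.363 with an estimated correlation).

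The deposited cell table records male for all 15053 cells. Xist, which is transcribed from the inactive X chromosome of females, had 31766 and 43104 UMIs in the control and 34986 and 38076 UMIs in the ketogenic libraries. The Y-linked genes Ddx3y, Eif2s3y and Uty had 0 UMIs in each library, and Kdm5d had 1 UMI in all 4 together. These counts argue against the record of male in all 4 libraries.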
